A study of Drosophila melanogaster with 2 samples.

How the data were processed

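ChIP-seq peaks of GFP-tagged Kr were analysed from mixed-sex whole embryos of 0 to 10 h, in 1 group of 2 biological replicates (numbers 2 and 3 per the labels). Per the labels, the line stably expresses Kr with GFP at its C terminus, chromatin was sonicated, and the tagged protein was precipitated with an antibody to GFP. The aligner, the peak caller and the threshold of the irreproducible discovery rate (IDR) are not given in the sources used here. Per the deposited text lists of files, permissive peak lists were called for each replicate and for the pooled reads of both, against a control file that is not analysed here, and an IDR list was made from them. Each exists for dm6 and dm3. The replicates were called separately, so they could be compared peak by peak.

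Peak height is the signal value deposited by the authors for each peak, of unknown scale. The authors' lists also hold the −log10 of a q-value for each peak, by the narrowPeak format named in the deposited text lists. In the IDR list, q was at most 0.00325, and in the pooled permissive list up to 0.763. The permissive lists thus hold many weak peaks by construction. The IDR list held 2102 peaks for dm6, in 1962 regions once overlapping peaks were merged, with a median width of 440 bp, and 1552 for dm3. In both builds the list was exactly the pooled peaks of highest signal, down to 103 in dm6 and 115 in dm3. The dm6 lists were the main source. The dm3 lists gave counts and replicate comparisons only, since no coordinates were converted. Chromosome names and lengths matched the dm6 sequence used here. Genes came from the Ensembl release of the BDGP6 assembly, of which 13968 protein-coding genes on the chromosome arms were used. Coordinates are dm6 and start at 1.

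Depth could not be given, since the files hold peaks and no counts. Shares carry Wilson 95% intervals and densities exact Poisson 95% intervals, both for counting error only. The 2 replicates are the only measure of biological spread, and the SD of 2 signal values includes the difference in scale between their lists.

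Replicates were compared by the share of IDR summits within 250 bp of a summit in each permissive list, by Spearman's rho of signal, and by the overlap of the 1000 highest peaks, with 100 circular shifts as background. Summits were assigned to a promoter (within 500 bp of a TSS of a protein-coding gene), 5′ UTR, coding exon, 3′ UTR, intron or intergenic sequence, in that order. They were compared with 1000 sets of positions drawn uniformly within the same chromosome, including sequence in which peaks may be hard to call. A gene was occupied when an IDR summit lay in its body or within 5 kb. Each of 15 gene lists was compared with 10000 random lists of protein-coding genes matched by decile of gene length. The tRNA genes were matched to protein-coding genes in the same way, hence to very short ones. The smallest p these lists allow is 1e-04 before adjustment. P-values were adjusted by Benjamini-Hochberg over lists, features or words. Of the listed names, 4 were translated to those of the annotation (among them h to hry and duf to kirre), and every listed gene was found. Words were sought within 100 bp of the summit on both strands, against windows centred 1 kb to either side that did not overlap another summit window. The signal rank correlation used 100000 permutations.

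The gene lists, the fixed words, the tests of the main comparisons and most other settings tried were set before the data were examined. Other counts were chosen after results were seen, among them the run of IDR peaks around Kr, ribosomal protein genes bound at their own TSS, rho over all pooled peaks and the search over words of 7 letters. The rule for named genes was set beforehand. It takes all gap, pair-rule and maternal or terminal genes, the 10 highest peaks with the gene of the nearest TSS, Kr, up to 4 members of each other list by signal (up to 3 for control lists), and up to 5 genes with the most summits. Acp26Ab, which shares its peak with Acp26Aa, and RpL14, RpL37A, RpS10b and RpL13A are named beyond the rule, chosen after their values were seen. Alternatives were other match distances, promoter widths, gene windows, word windows and words, the 1051 highest IDR peaks, dm3 lists, and each replicate's own 2102 highest peaks in place of the IDR list. Random positions as background of the word were planned as well. Pooled summits outside the IDR list as comparator, and leaving out the peaks within 20 kb of Kr, were added after seeing the data. With 1 group there was no comparison between conditions.

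The tests were tested on simulated data. For the replicate comparison, all of 2000 simulated summits moved by up to 200 bp were matched (100%), and 0.85% after a shift. For gene lists, 1.5% of 200 random lists of 10 genes had an upper p under 0.05 before adjustment, and 100% of 200 lists with 7 planted genes. The Results use adjusted p instead. Occupancy of 7 in 10 is above that of the lists that did not pass, so the power to detect those is not covered. The simulated lists were scattered genes with summits placed uniformly, so the rates do not cover clustered genes that share peaks. For the features, 2000 random summits gave a promoter ratio of 1.04, and planting 10% of them on TSSs gave 21.5% in promoters, where 20.3% was expected by construction. For the word, 2000 random summits gave a ratio of 1.13 (Fisher's exact test, p = 0.597), and planting it in 10% of windows raised the share by 9.9 percentage points. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.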

Results

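Binding of Krüppel (Kr) was mapped by ChIP-seq in whole Drosophila melanogaster embryos of mixed sex, collected 0 to 10 h after laying. Kr is a gap-gene zinc finger that acts mainly as a repressor and positions the segmentation genes of the early embryo. The embryos came from a transgenic line carrying Kr with a GFP tag at its C terminus, and the tagged protein was precipitated with an antibody to GFP. The series held 1 group with 2 biological replicates, numbered 2 and 3 in the labels. For each replicate, and for both pooled, a permissive list of 30000 peaks on the dm6 genome was used. A further list of 2102 peaks, called IDR peaks below, was the authors' set thresholded by irreproducible discovery rate, made from both replicates. It held exactly the pooled peaks of highest signal, so its peaks need not each be high in both replicates. The files give peaks and no read counts, so the sequencing depth of each library is unknown, and intervals on shares cover counting error only. Peak height is the authors' signal value, of unknown scale, and serves to describe and rank peaks within its own list. Means over the replicates and the ratio between them take it as linear.

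The gap genes, which divide the early embryo into broad territories and cross-regulate each other, carried IDR peaks at 5 of 7 members. Among 10000 random lists of protein-coding genes of matched length the median was 1 of 7 (upper permutation test, Benjamini-Hochberg adjusted p = 0.00814 over 15 lists). The strongest was at giant (gt), a gap gene that Kr represses and that represses Kr, whose peak at X, 2429056 to 2429237 lay in the promoter, 184 bp from the transcription start site (TSS). It ranked 53 in the IDR list with a signal of 358, and had 215 and 150 in replicates 2 and 3 (mean 182 ± 45.9, SD, n = 2). The peak at knirps (kni; 3L, 20696592 to 20696747) was intergenic, 1321 bp from the TSS, and ranked 150 with 148 and 119 in the replicates. At hunchback (hb; 3R, 8701245 to 8701684) an intergenic peak 3643 bp from the TSS ranked 159, with 163 and 94.9 in the replicates. The best of 2 peaks at tailless (tll; 3R, 30849488 to 30849927), a terminal gap gene, was intergenic and ranked 1048, with 92.6 and 42.1. Each of the top peaks at gt, kni, hb and tll had the Kr core word AAGGGTT within 100 bp of its summit. No IDR peak lay in huckebein (hkb) or knirps-like (knrl) or within 5 kb of them. Their best pooled peaks ranked 3342 and 4351 of the 30000, below the IDR list. Without replicate 2, in the 2102 highest peaks of replicate 3, tll had 0 summits, 4 of the 7 gap genes were occupied and the adjusted p was 0.0583 by the same permutation test.

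Kr itself (2R, 25226611 to 25231394) had 3 IDR peaks in its body or within 5 kb. The highest of them lay in the promoter, 242 bp from the TSS at 2R, 25226149 to 25226588. It ranked 890 with a signal of 143, had 85.3 and 82.7 in replicates 2 and 3 (mean 84.0 ± 1.89, SD, n = 2), and lacked the word. Much higher binding lay 11275 bp from the Kr TSS, inside an intron of CG9380, the long gene in which Kr is embedded. That peak (2R, 25215126 to 25215555) carried the word and ranked 4 of all IDR peaks, with signals of 664 and 497 in the replicates, where it also ranked 4. A run of 30 IDR summits with gaps under 10 kb covered 52.4 kb from 25192410 to 25244796. Within 20 kb of Kr there were 17 IDR summits, against a median of 0 in 1000 windows of the same size centred on random genes. The permissive lists had 54 and 47 summits there, against medians of 9 and 10. The tagged gene is introduced at this locus or as a further copy of it, which the labels do not settle. With all peaks within 20 kb of Kr left out, 2085 IDR peaks remained and 4 of 7 gap genes were occupied (permutation test, adjusted p = 0.0480). Kr itself stayed in the list, so its own loss was fixed by that removal.

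**Figure D1:**
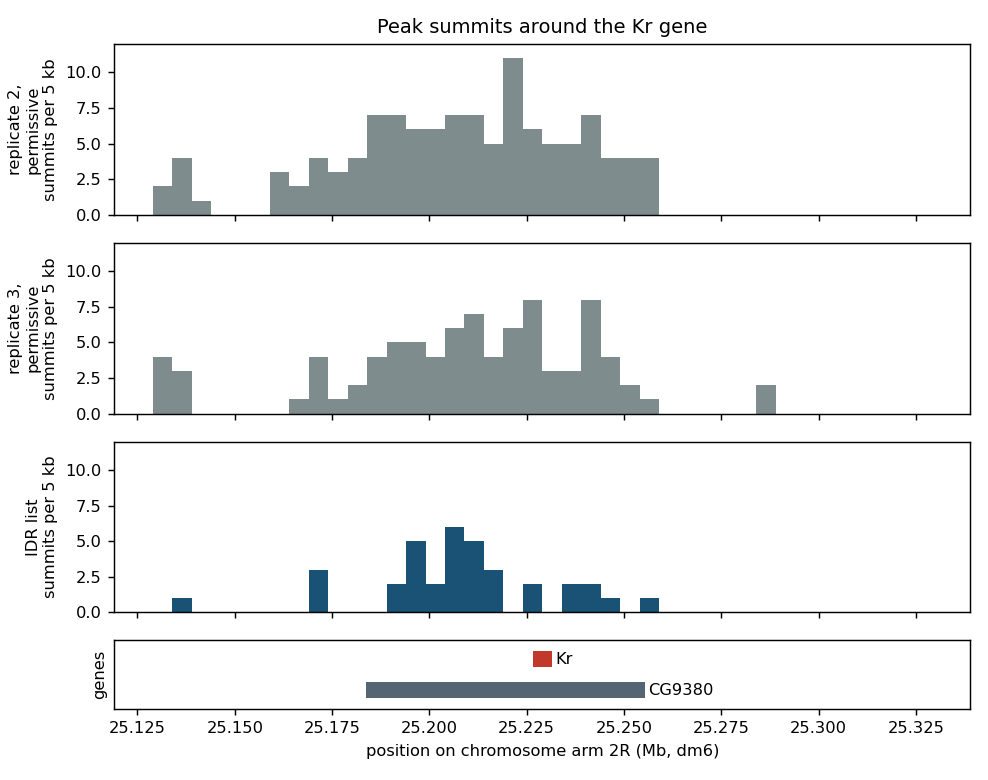
Peak summits per 5 kb along chromosome arm 2R (Mb, dm6) around Kr, for the permissive lists of replicates 2 and 3 and for the IDR list, with the bodies of Kr and CG9380 below. IDR summits are densest on the left of Kr, within the run that starts at 25192410, where single bins hold up to 6. The arm ends at 25286936, and the axis runs past it, so the empty bins beyond that point hold no sequence.

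The list of pair-rule genes, which draw the first periodic stripes, was occupied at 9 of 11 members. The random median was 2 (permutation test, adjusted p = 0.000375, from the smallest p that 10000 lists allow). Sloppy paired 2 (slp2) had the highest peak (2L, 3832440 to 3832606, intergenic), ranking 102 with 142 and 144 in replicates 2 and 3. The best peak of drumstick (drm) ranked 387 with 84.1 and 113, and that of odd-paired (opa), in an intron and 1 of 5 at the gene, ranked 441 with 133 and 55.2. The intergenic peak of sloppy paired 1 (slp1) ranked 454 with 135 and 46.1. Paired (prd) and odd skipped (odd) ranked 589 and 608, with 104 and 57.4 at prd and 98.2 and 71.1 at odd. Sister of odd and bowl (sob), hairy (hry in the annotation) and fushi tarazu (ftz) ranked 1360, 1374 and 1535. Replicate signals were 53.4 and 72.5 at sob, where the nearest TSS was that of CG43815, 83.9 and 45.8 at hry, and 70.6 and 43.6 at ftz, where the peak lay in the promoter. Even skipped (eve) and runt (run) had no IDR peak. Their best pooled peaks ranked 3229 and 2611, with q of 0.00945 and 0.00555 in the authors' list. Calls at single genes moved without replicate 2, where eve had 1 summit and ftz 0. None of the 9 best peaks of this list had the word. The list also held drm and sob, relatives of odd that are not classic pair-rule genes, and both were among the 9.

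Maternal and terminal factors were occupied at 5 of 9 members against a random median of 2 (permutation test, adjusted p = 0.0283). These were capicua (cic, a repressor of terminal genes), bicoid (bcd, the anterior morphogen), caudal (cad), groucho (gro, a co-repressor) and tll. The best peak of cic, in an intron, ranked 162 with 170 and 84.0 in replicates 2 and 3. That of cad, also intronic, ranked 343 with 105 and 98.3. The best peak near bcd (rank 312, 123 and 101) lay in the promoter of the neighbouring Ama. The best near gro (rank 597, 124 and 54.5) lay in the promoter of E(spl)m8-HLH. Nanos (nos), oskar (osk), torso (tor) and hkb had none. The best pooled peaks of nos and osk ranked 3657 and 2693, and tor had 0 pooled peaks. Without replicate 2 the count was 4 of 9, with 0 summits at tll, and the adjusted p by permutation was 0.127. Without replicate 3, osk had 1 summit.

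Of the head gap genes, which pattern the anterior head, 7 of 8 were occupied (random median 2, permutation test, adjusted p = 0.000375). Besides slp2 and slp1 these included Dichaete (D, rank 330), a Sox factor, and empty spiracles (ems, rank 771), a homeobox gene with its peak in the promoter. The list of Hox genes, which set segment identity, also held bcd, zen and zen2, genes of the same cluster that do not. It was occupied at 8 of 11 (random median 3, permutation test, adjusted p = 0.00750), with bcd and zen among the 8, and was led by labial (lab, rank 301), bcd (by the peak at Ama), Antennapedia (Antp, rank 340) and abdominal-A (abd-A, rank 348). The abd-A peak, in an intron, had the word. Segment-polarity genes, which keep parasegment borders, were occupied at 8 of 14 (random median 4, permutation test, adjusted p = 0.0312). The Wnt feedback gene naked cuticle (nkd) ranked 217, the Hedgehog receptor gene patched (ptc) 283, engrailed (en) 357 and cubitus interruptus (ci) 426. Without replicate 2 the same count of segment-polarity genes gave an adjusted p of 0.0508 by permutation.

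In the main setting, the neural list and the tracheal, gut, salivary and blood list passed too. The mesodermal, dorsoventral and early zygotic lists did not. Neuroblast and neural markers were occupied at 12 of 18 (random median 4, permutation test, adjusted p = 0.000375). The temporal factor pdm2, active in the neuroblast series that also uses Kr, had the best of them (rank 94, 2L, 12681858 to 12682297, intronic, with the word). It was followed by grainy head (grh, rank 230), elav (rank 247) and nerfin-1 (rank 282). Tracheal, gut, salivary gland and blood markers were occupied at 8 of 14 (random median 4, permutation test, adjusted p = 0.0283). U-shaped (ush) had 8 summits and rank 26, and fork head (fkh), a foregut and hindgut factor, had a promoter peak of rank 51. Brachyenteron (byn) ranked 1189, by a peak in an intron of CG44837, and peb 1387. Without replicate 3 that list fell to 7 of 14 with an adjusted p of 0.0661 by permutation. Dorsoventral genes did not pass at 8 of 18 (random median 4, permutation test, adjusted p = 0.0713). Their best peaks were at brinker (brk, rank 22, in an intron of CG1677, with the word) and single-minded (sim, rank 74), and at decapentaplegic (dpp) and Doc1, with ranks of 885 and 989. That list passed with either replicate alone, at 10 of 18 in both, with adjusted permutation p of 0.0160 without replicate 2 and 0.00483 without replicate 3. Mesoderm and muscle markers did not pass at 6 of 15 (random median 4, permutation test, adjusted p = 0.238). Their best peaks were near Mef2 (rank 218, in the promoter of Pdrg1), kirre (rank 539), kn (rank 675) and slou (rank 1597). The list of early zygotic genes, not all of them genes of cellularization, did not pass at 3 of 9 (random median 1, permutation test, adjusted p = 0.205). The 3 were Z600 (rank 334, in the promoter of CG7841), Sry-alpha (rank 1685), whose peak sits at the RpL32 promoter, and sisA (rank 1877). Without replicate 3 that list had 4 of 9 and an adjusted p of 0.0430 by permutation.

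The control lists went different ways. Odorant and gustatory receptor genes were occupied at 6 of 119 against a random median of 17 (lower permutation test, adjusted p = 0.0165), for example Gr5a (rank 192, in an intron of Tre1), Gr93a (rank 293, intergenic) and Or85f (rank 308, in an intron of FER). The lower count did not pass with either replicate alone, at 10 genes without replicate 2 (permutation test, adjusted p = 0.157) and 8 without replicate 3 (adjusted p = 0.412). Adult-restricted genes of eggshell, yolk, eye, seminal fluid and olfaction, a list that shares odorant receptor genes with the one before, had 4 of 36 (random median 5, upper permutation test, adjusted p = 0.802), which were the rhodopsin gene Rh5 (rank 187), Yp3 (rank 754, in the promoter of Pdcd4) and the paired Acp26Aa and Acp26Ab (1 shared peak, rank 2033). None of the 4 is a receptor of smell or taste. Ribosomal protein genes were occupied at 44 of 82, against a random median of 11 (upper permutation test, adjusted p = 0.000375). RpS27 had its summit 13 bp from its TSS (rank 64; 167 and 164 in replicates 2 and 3), and RpL7 7 bp away (rank 132; 133 and 135). The highest in the list, near RpL22 (rank 50), lay in the promoter of CG5273. At 39 of the 82 genes (47.6%) an IDR summit lay within 500 bp of the gene's own TSS with no TSS of another gene nearer, which held for 3.72% of other protein-coding genes. Transfer RNA genes were occupied at 48 of 290 (random median 28, upper permutation test, adjusted p = 0.000600), led by tRNA:Tyr-GTA-1-6, tRNA:Tyr-GTA-1-7 and tRNA:Tyr-GTA-1-8 near 1 peak of rank 39. That peak lay in the promoter of CG8036, and 7 IDR summits in all lay within 500 bp of a tRNA gene. Of all 13968 protein-coding genes, 2516 (18.0%) were occupied. Clustered genes share peaks, so members of a list are not independent.

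**Figure D2:**
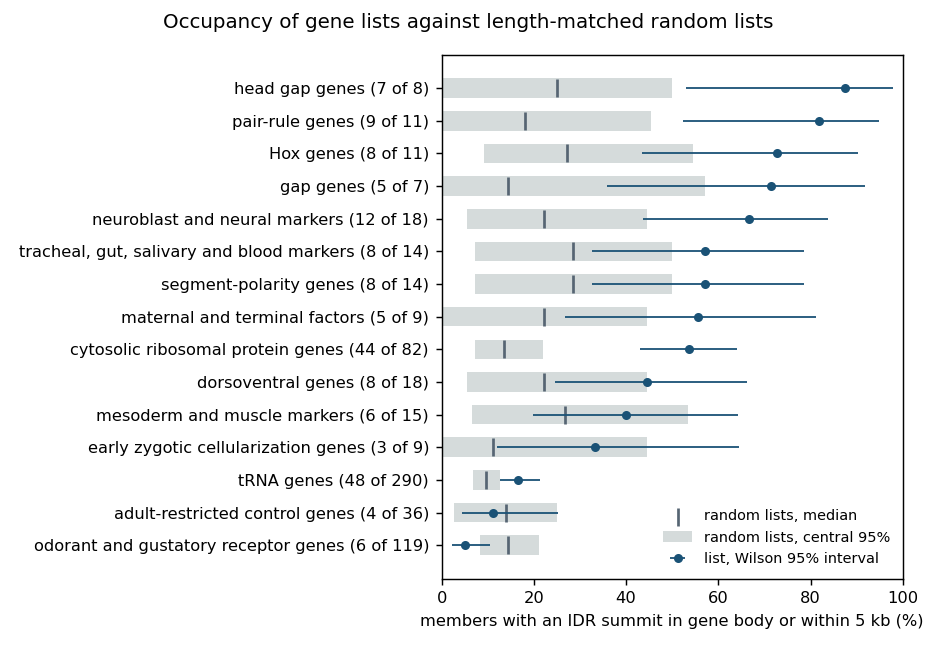
Percentage of each gene list with an IDR summit in the gene body or within 5 kb (points, with Wilson 95% intervals), beside the median and central 95% range of 10000 length-matched random lists. Head gap genes (7 of 8) and pair-rule genes (9 of 11) lie farthest above their random ranges, and odorant and gustatory receptor genes (6 of 119) lie below theirs.

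The lists also allowed a comparison of segmentation genes with genes of later tissues. Of 45 genes in the maternal, gap, head gap, pair-rule and segment-polarity lists, 31 (68.9%) were occupied. Of 47 genes in the neural, mesodermal and tracheal, gut, salivary and blood lists, 26 (55.3%) were. The odds ratio was 1.79 and the difference did not pass (two-sided Fisher's exact test, p = 0.203). Unlike the list tests, this comparison was not matched by gene length. The length-matched random medians were 2 of 9, 1 of 7, 2 of 8, 2 of 11 and 4 of 14 for the segmentation lists. For the later lists they were 4 of 18, 4 of 15 and 4 of 14, all in the order given above. Length may thus hide a difference, and equal occupancy cannot be read from this test. Among the 1051 highest IDR peaks the counts were 22 of 45 and 12 of 47, with an odds ratio of 2.79 (Fisher's exact test, p = 0.0303). That p was not adjusted over settings, and no other alternative passed (Fisher's exact test, p from 0.123 to 0.404).

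The highest IDR peak of all (3R, 17604497 to 17605211) was intergenic, 1233 bp from the TSS of sll, a sulphate nucleotide transporter gene. It had signals of 1283 and 729 in replicates 2 and 3, and carried the word. The peak ranked 2 (2L, 14588805 to 14589271, intergenic) lay 795 bp from CG42680 and had the word, with 935 and 869. The peak ranked 3 was in an intron of CG6191 and lacked the word, and the peak ranked 5, in the promoter of Gpat4, had it. A single stretch of 2R held peaks 3, 6, 7 and 8, from 13561624 to 13585018. The nearest TSS of peak 6 was that of CG42807, and that of peaks 7 and 8 was CG13334. Peaks 9 and 10 lay in the 5′ UTR of CG44838 and in an intron of sbb (also called brakeless, a co-repressor). By number of summits in the gene body or within 5 kb, CG9380 led with 31, followed by the zinc-finger gene jing with 21, sbb with 14, tara with 13 and homothorax (hth) with 12. These genes are 34679 to 132008 bp long.

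Of the 2102 IDR summits, 2079 (98.9%, Wilson 95% interval 98.4 to 99.3) had a summit within 250 bp in both replicates' permissive lists. The IDR list is the top of the peaks called on the pooled reads of these same replicates. The permissive lists hold 30000 peaks each, so a high share is built in. After 100 circular shifts of the IDR summits, a mean of 10.3% matched replicate 2 and 10.7% matched replicate 3. The share matched in both had a mean of 1.08% and a maximum of 1.62%. The shifts were drawn separately for each replicate, so this joint share ignores sites that the 2 permissive lists have in common. A shift shared by both replicates, which was not run, could match more often. The 2102 IDR peaks were exactly those of highest signal in the pooled list. By rank, 1133 (53.9%) stood among the 2102 highest peaks of both replicates. Across the matched IDR peaks the replicates' signals had a Spearman rho of 0.35 (bootstrap 95% interval 0.310 to 0.390). Over the 15758 pooled permissive peaks matched in both replicates, a wider range of signal, rho was 0.485. Peaks are not independent replicates, so no p is given. Signals in replicate 2 were a median of 1.46 times those in replicate 3, with a SD of 0.64 in the log2 ratio. Of the 1000 highest peaks of replicate 2, 62.3% (Wilson 95% interval 59.3 to 65.3) lay within 250 bp of the 1000 highest of replicate 3, against a mean of 0.364% after shifting.

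**Figure D3:**
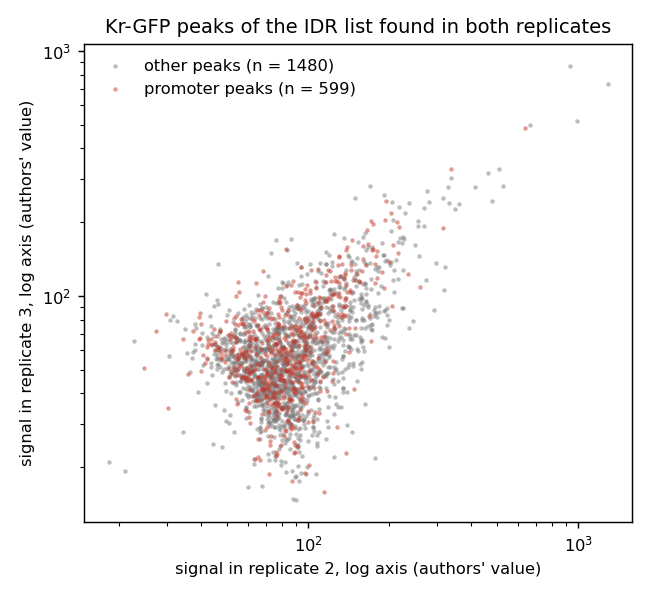
The authors' signal in replicate 2 against replicate 3, both on log axes, for the 2079 IDR peaks found in both replicates, with promoter peaks marked. The highest peak in the IDR list, near sll, stands at 1283 and 729. Points scatter widely, with a rho of 0.35 over all of them and 0.354 among the 1051 highest IDR peaks.

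IDR summits were concentrated at promoters and nearly absent from coding sequence. Within 500 bp of an annotated TSS lay 607 summits (28.9%), 2.52 times the mean of 1000 sets of random positions on the same chromosomes (11.5%). Coding exons held 9 summits (0.428%, against 13.9% of random positions) and 3′ UTRs 12 (0.571%, against 4.42%). For all 3 the two-sided permutation test gave the smallest p that 1000 sets allow (0.00200, adjusted 0.00400). The contrasts were smaller against pooled summits outside the IDR list, a comparator chosen after the data were seen. Of those, 18.6% lay in promoters (ratio 1.55), 7.62% in coding exons and 2.17% in 3′ UTRs (permutation test, adjusted p = 0.00400 for each). Introns held 865 summits (41.2%, random 39.1%), as at opa and nkd, and did not pass (permutation test, adjusted p = 0.0575). The 590 intergenic summits (28.1%, random 30.4%), such as those at hb and slp2, had an adjusted permutation p of 0.0360. That call ended with either replicate alone (28.2% without replicate 2, permutation test, adjusted p = 0.0569, and 29.1% without replicate 3, adjusted p = 0.204), while introns passed without replicate 3 (41.6%, adjusted p = 0.0420). The 5′ UTRs outside promoters held 19 summits (0.904%, random 0.778%, permutation test, adjusted p = 0.583).

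The Kr core word AAGGGTT, or its reverse complement, lay within 100 bp of 263 of the 2102 IDR summits (12.5%, Wilson 95% interval 11.2 to 14.0). In windows of the same width 1 kb to either side it was found in 86 of 4005 (2.15%), a ratio of 5.83 (two-sided Fisher's exact test, p = 2.76e-58). Tests of words against flanks take all windows as independent, although each flank belongs to a summit and some peaks overlap. The size of the ratio depended on the setting. It was 9.53 within 50 bp, 3.57 within 200 bp and 3.27 for a shorter word. Against pooled summits outside the IDR list, of which 4.39% had the word, it was 2.85 (Fisher's exact test, p = 5.75e-46, comparator chosen after the data were seen). Among the 210 arrangements of its letters it ranked 2 by ratio, behind AGGGTTA (5.90), which overlaps the same longer site. Of 4791 words of 7 letters, it ranked 1 by p. The word was most frequent in the 25 bp just before the summit (71 summits, 3.38%). It stood in peaks at gt, kni, hb, tll, brk, pdm2, nkd and abd-A, and was missing from those at slp2, cic, ush and fkh.

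**Figure D4:**
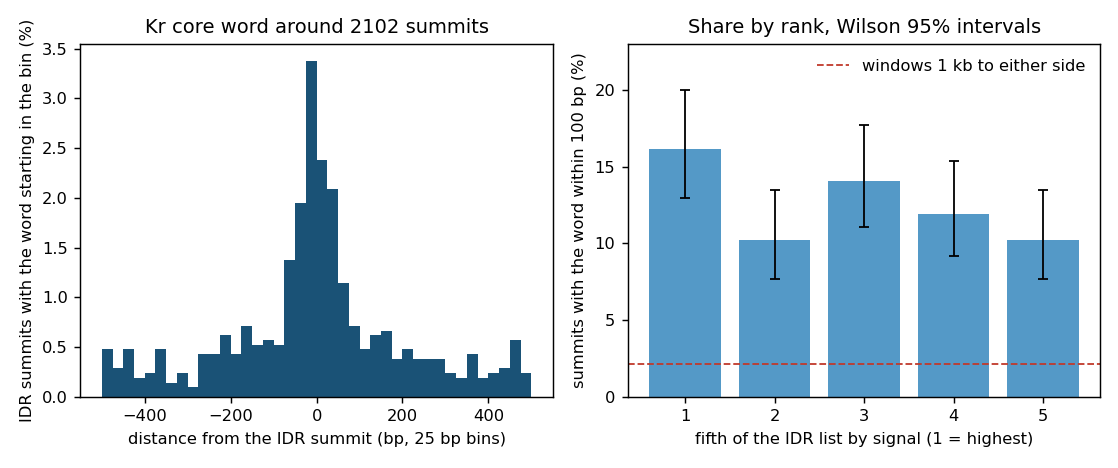
Left, percentage of 2102 IDR summits with the Kr core word starting in each 25 bp bin around the summit. Right, percentage with the word within 100 bp by quintile of the list by signal (Wilson 95% intervals), with the share in windows 1 kb away as a dashed line at 2.15%. Every quintile, from 10.2% to 16.2%, lies above that line.

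Of the 8 other words tested, 2 passed. The Zelda word CAGGTAG, bound by the factor that opens the early embryonic genome, was in 3.28% of summit windows and 1.32% of flanks (ratio 2.48, Fisher's exact test, adjusted p = 1.75e-06). The GAGA factor word GAGAGAG was in 9.37% and 3.50% (ratio 2.68, Fisher's exact test, adjusted p = 8.61e-20). Bicoid (GGATTA, ratio 0.896), Hunchback (CATAAAA, 1.02), Caudal (TTTATGG, 0.901), the Giant type (TTACGTAA, 1.43) and the TATA box (TATAAAA, 0.904) had adjusted p from 0.430 to 0.851. The Twist-type E-box CATATG had a ratio of 1.24 and an adjusted p of 0.0694.

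The share of peaks with the Kr word was 16.2% in the highest quintile of the IDR list, 10.2% in the next, then 14.0%, 11.9% and 10.2%. Across peaks, the rank correlation of signal with the word was 0.0521 (permutation test with 100000 resamples, p = 0.0168). Promoter peaks had the word less often than distal peaks. It stood in 56 of 607 summits within 500 bp of a TSS (9.23%), such as gt, and in 159 of 1088 over 2 kb away (14.6%), such as hb and tll, an odds ratio of 0.594 (two-sided Fisher's exact test, p = 0.00135). The flanks differed in the same direction, with the word in 1.44% at promoters and 2.67% at distal peaks. Against their own flanks the ratios were 6.41 and 5.47, and the difference between these ratios was not tested.

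IDR peaks were sparse on the X chromosome, home of gt, brk and run. It had 236 peaks, or 10.0 per Mb (exact Poisson 95% interval 8.79 to 11.4). The arms 2L, 2R, 3L and 3R had 19.5, 15.9, 17.1 and 16.0 per Mb. The X density was 58.9% of that of these 4 arms together, while X carried 87.1% of their density of protein-coding genes. Chromosome 4, home of ci, had 11 peaks, or 8.16 per Mb (4.07 to 14.6), and the Y had 0. The X held 11.2% of IDR peaks (Wilson 95% interval 9.95 to 12.6).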

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

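The tests of Kr words near Kr and of the word at ribosomal protein promoters were chosen after the patterns they bear on had been seen.

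The dm3 IDR list held 6 peaks on sequence outside the named chromosome arms. They count among the 1552 peaks of the dm3 alternatives. Of these, 5 lay on Uextra (best rank 211 of 1552, signal 239) and 1 on 3LHet (rank 453, signal 182). They drew attention as more than the 3 that a count of 0 allows. Where this sequence lies in dm6 is not analysed here, and no explanation was tested.

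Peaks crowd around Kr itself, with 54 and 47 permissive summits within 20 kb in replicates 2 and 3. Both counts lie at the 99.9th percentile of 1000 windows centred on other genes. Extra copies of the region carried by the transgene might give this, but these counts are the pattern itself and lend no separate support. A high density of binding sites also remains open, since the 13 Kr words in the same window lie at percentile 99.4 (median 4). The IDR peaks nearby had the word at 3 of 17 (17.6%, Wilson 95% interval 6.19 to 41.0), against 12.5% of all IDR peaks, and no control library was used here that would settle the copy number.

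IDR peaks favour promoters, and the ribosomal protein and tRNA lists were occupied beyond random lists (adjusted p = 0.000375 for ribosomal proteins, permutation test). If open promoters were recovered without any binding by Kr, the word should be no more frequent there than nearby. Promoter peaks had it 6.41 times as often as their own flanks (two-sided Fisher's exact test, p = 2.66e-14). On that premise, this argues against open promoters as the account of every promoter peak. The flanks are a limited control, since 307 of 4791 words of 7 letters exceeded theirs at IDR summits. Some of these were not pieces of the Kr site, such as CGCTCTC with a ratio of 3.46. Promoter summits outside the IDR list were not used as comparator. The word stood in only 56 of 607 promoter peaks (9.23%, against 1.44% of flanks). For promoter peaks without the word, recovery without Kr remains open. Highly transcribed loci recovered whatever the antibody remain open for both lists, whose occupancy does not tell this from binding by Kr. Only 7 IDR summits lay within 500 bp of a tRNA gene, and 0 of them had the word (Wilson 95% interval 0 to 35.4). The 42 peaks within 5 kb had it at 11.9%, against 12.5% of all IDR peaks. At ribosomal protein promoters the word was in 1 of 39 peaks (2.56%, Wilson 95% interval 0.454 to 13.2) and in 9.68% of other promoter peaks (Fisher's exact test, p = 0.245), so 39 peaks leave open whether the word brings Kr there. With 1 group in the design, no difference between conditions was tested.

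IDR peaks were sparse on X, at 58.9% of the density of the large autosomal arms. Kr words per Mb on X were 101.5% of the autosomal density, which argues against fewer words there. Lower X copy number in embryos of mixed sex may account for it. If signal, whose scale is unknown, is taken as linear in copy number and X signal is multiplied by 4/3, the X density above the IDR cutoff reaches 124.5% (exact Poisson interval 113.8 to 136.0), past the autosomal arms. On that assumption a smaller loss of signal would already level the arms, and the permissive list had 83.9% without any scaling. The scaling took X from 236 to 499 peaks, so the count near the cutoff is very sensitive to signal. The result therefore does not tell copy number from other causes of lower X signal. Peaks were also called against a control file, and whether the signal already allows for X copy number is unknown.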

How the results depend on the processing

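The comparator of pooled summits outside the IDR list and the removal of peaks within 20 kb of Kr were chosen after the data were seen; all other alternatives were planned. Of 310 recomputed values, 240 kept their side of the threshold or their range, and 0 reversed a result that had passed. The promoter, coding exon and 3′ UTR shares, the head gap, pair-rule, neural, ribosomal protein and tRNA lists, the Kr word at summits, its rank trend and its promoter to distal difference, and the X share did so under every alternative run on them. Results that passed in neither setting could change direction and still count as kept. Introns did, with a ratio of 0.987 for promoters of 1000 bp against 1.05 in the main setting. The dm3 count of 1552 peaks against 2102 in dm6 was kept too, because ratios up to 1.5 were. The tally also holds values that could hardly change. Among these are genes such as tor with 0 summits in every setting, and most lists after the loss of only 17 peaks near Kr. The 240 of 310 is thus no measure of robustness. The 1051 highest peaks are fewer by construction, and replicate agreement there was 99.4%. Agreement was 89.2% within 100 bp, 99.7% within 500 bp and 93.1% by reciprocal overlap of 50%, where rho was 0.281. The top overlap was 58.9% for 2000 peaks and 54.3% within 100 bp. With promoters of 250 bp, introns passed (45.2%) and intergenic sequence did not (30.5%). The intergenic share did not pass among the 1051 highest peaks (28.2%) or against pooled summits outside the IDR list (ratio 0.978). Without a replicate intergenic shares ranged from 28.2% to 29.1% and intron shares from 40.01% to 41.6%. With gene windows of 2 kb, receptor genes (3) and the tracheal, gut, salivary and blood list (6) no longer passed. By nearest TSS, dorsoventral (9) and mesodermal genes (6) passed, and maternal and terminal (3) and receptor genes (5) did not. Among the 1051 highest peaks, Hox (4), receptor (4), segment-polarity (5) and tracheal, gut, salivary and blood genes (2) did not pass, and the segmentation odds ratio of 2.79 did. Without a replicate, occupied genes ranged from 10 to 10 (dorsoventral), 4 to 5 (gap), 4 to 6 (maternal and terminal), 8 to 10 (receptor), 8 to 9 (segment-polarity), 3 to 4 (early zygotic) and 7 to 8 (tracheal, gut, salivary and blood). The causes were not tested. Of 143 values for single genes or minor features, 34 counts of summits moved by over 1.5 times, and the 5′ UTR share passed with promoters of 250 bp (2.24%). No paired analysis was possible because there is only 1 group. Depth is unknown, so no limit from it can be given.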

Other observations

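The word counts in this part were chosen after results were seen, and none of them was a planned comparison.

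Beyond the fixed words, 307 of 4791 words of 7 letters were more frequent at IDR summits than in their flanks and 161 less frequent (Fisher's exact test, Benjamini-Hochberg adjusted p under 0.05). The leading ones were pieces or close variants of the Kr site, with AAAGGGT in 13.1% of summits and 2.65% of flanks (ratio 4.96), AGGGTTG in 7.18% and 1.22% (ratio 5.87) and AAGGGGT in 8.47% and 1.82% (ratio 4.65). A second family was GA-rich, with CGCTCTC in 8.04% and 2.32% (ratio 3.46), beside the GAGA factor word itself, CTCTCTC on the other strand. Another held GCAAACA, with 14.1% and 6.79% (ratio 2.07), and ACAAACA, with 14.3% and 7.39% (ratio 1.93). CACACAC repeats were in 14.0% and 7.34% (ratio 1.91). No factor was assigned to the last 2 groups here.

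Summits at gene starts of ribosomal proteins lay closer to the TSS by median, a difference that was not tested. The 39 IDR summits at their promoters lay a median of 14 bp from the TSS, with a median signal of 152, against 161 bp and 134 at the other 568 promoter peaks. RpL14 and RpL37A had summits 2 bp from the TSS, and RpS10b and RpL13A 3 bp. The 42 IDR peaks within 5 kb of a tRNA gene were close to all IDR peaks, with a median of 2008 bp to the nearest protein-coding TSS (2134.5 bp for all) and the Kr word in 11.9% (Wilson 95% interval 5.19 to 25, against 12.5% for all).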
